A study of Mus musculus with 65 samples.

How the data were processed

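RNA was measured in 26 bulk and 31 single-cell libraries and histone marks in 8 ChIP samples, deposited as 63 processed files. The bulk RNA-seq values are RSEM expected counts per ID, per the file headers. The single-cell values are expected counts per ID and cell barcode as deposited, most of them whole numbers. The day 2 pair of separate R1 libraries instead holds TPM per cell, which the authors scaled so that every cell sums to the same total. Per the submitters' processing notes, reads were aligned with Bowtie and quantified with RSEM on the mm9 build, single cells were handled with Seurat 2.4, and ChIP data with HOMER and bedtools; the versions of Bowtie and RSEM are not given in the sources used here. The names of the RA day 4 single-cell files, however, give GRCm38 Ensembl for some and mm9 for others, so the build may differ between files. The ZHBTC4 bulk files and 15 of the single-cell files carry Ensembl IDs, of which 55104 of 55364 had a symbol in the reference table. The R1 bulk files and the other single-cell files carry UCSC transcript IDs, of which 0 of 55116 were found in the reference tables, so no gene names were used for them.

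The deposited ChIP promoter files give, per gene symbol, 100 bins of whole numbers, read here as signal; bin width, span and whether the numbers are reads or coverage are not given in the sources used here. Repeated regions among the 47192 entries were counted once, which left 32771 regions, with totals of 11519116 (KO) and 8754290 (WT) for H3K4me1 and 25490473 (KO) and 38373635 (WT) for H3K4me2. The deposited enhancer lists give a chromosome, start, end and 1 score per region. Each mark and genotype has 1 pooled column, so replicate samples could not be separated. One single-cell KO sample (ZHBTC4 replicate 2) had no values and was not used here.

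Samples were grouped by the labels, and the comparisons, tests, gene lists and the rule for naming genes were chosen before the data were examined. The rule names Esrrb, the strongest members of each list past the threshold in each direction, and the largest changes among genes whose libraries do not overlap between groups and whose mean CPM in the higher group is at least 10; predicted genes and pseudogenes were passed over in the last part. Pou5f1 in both protocols and Gata4, Sox17 and Foxa2 in XEN differentiation were chosen after their values were seen. So were Mki67 in chemical medium and the genes compared between WT groups of the protocols. The day of 2 bulk groups comes from sample titles, and one pair of single-cell libraries is titled day 4 and annotated day 2; the title was used.

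Expected counts were rounded to whole numbers. Single-cell counts were summed over the barcodes of each library with at least 500 counts; no doublets were removed. Differences were tested with edgeR 4.0.16 (R 4.3.3): filterByExpr, TMM factors, the quasi-likelihood F test and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of F. Of 22 gene lists, 21 (20 in chemical medium) were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Sensitivity to the method was tested with DESeq2 1.42.0, RLE size factors, no filter on low counts, the replicate number as a block, other sets of libraries in the fit, other minimums per barcode and leaving out each library. Alternatives added after seeing the data were IDs with the same symbol summed, libraries thinned to the smallest total, libraries of the same cells kept apart, removal of an ID that takes over 50% of the counts of a library, and other rules for the overlap of enhancer lists. Each test was first tested on simulated counts with 200 changed genes.

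Several libraries of one group held the same barcodes: 100% of the smaller ZHBTC4 WT library, 42.4% for G1 in chemical medium, 72.2% for day 2 G1 and 98.8% for day 2 G2. Libraries of a group sharing over 40% of barcodes were counted as 1 sample, with their mean. This left 1 sample per group for ZHBTC4 KO against WT and for day 2 G2 against G1, so these planned tests, and that of the difference between days, were replaced by values. The RA day 4 groups have 1 library with Ensembl IDs and 1 with UCSC IDs that could not be joined, so their planned tests were replaced as well. For groups of 1 sample, log2 ratios of CPM use a pseudocount of 0.5 CPM, intervals are exact Poisson for counts, and a list's median is given as its percentile among 10000 random lists of the same size matched on mean expression. Genes of the largest ratios had at least 50 CPM in the higher library.

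A XEN-marker cell had at least 3 of 24 XEN genes after thinning to 1000 counts, with exact Clopper-Pearson 95% intervals. Libraries with under 50 cells of at least 1000 counts were given no share, and 1 cell of the RA day 4 G2 library was too shallow. Cells were also clustered (Leiden, 30 principal components, 15 neighbours, 2000 variable genes, resolution 1.0; 7547 cells, 15 clusters, 3 of them XEN-like). Shares between groups were compared by two-sided exact permutation tests over samples. ChIP ratios were taken after scaling KO and WT to the same total, with pseudocounts of 25.5 (H3K4me1) and 25.0 (H3K4me2), the 10th percentile of nonzero values. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, leidenalg 0.10.2, matplotlib 3.10.9 and bedtools 2.31.1 were used.

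A fold against a group with 0 counts is given as a lower bound against a floor of 3 counts over the group. Bulk libraries held 58302 to 44714502 counts; the single-cell libraries held 16674 barcodes, with library medians of 861 to 16998 counts per barcode.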

Results

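The series holds 65 samples of mouse embryonic stem (ES) cells: 26 bulk RNA-seq libraries, 31 single-cell RNA-seq libraries and 8 chromatin immunoprecipitation (ChIP) samples. Cells of the R1 line carried the FUCCI reporter, a pair of fluorescent proteins degraded at different stages of the cell cycle, and were sorted by stage before and during differentiation with retinoic acid at 1 µM. ZHBTC4 cells, an ES line whose Pou5f1 comes from a transgene that tetracycline shuts off, were compared with and without a knockout of Esrrb, an orphan nuclear receptor of the naive pluripotency network. The ZHBTC4 cells were differentiated for 9 days towards extraembryonic endoderm (XEN) or for 14 days as embryoid bodies (EB).

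The R1 bulk libraries held 10451233 to 20996960 counts at day 0 (3 late G1, 3 G2M) and 9864726 to 16371125 at day 2 (2 G1, 2 G2). At day 4 the 2 G1 libraries held 58302 and 5802361 counts and the 2 G2 libraries 2442344 and 3275068. The ZHBTC4 bulk libraries, 3 per group, held 13184089 to 31510941 counts for XEN wild type (WT), 25746025 to 44714502 for XEN knockout (KO), 2682064 to 8758995 for EB WT and 20646645 to 21758927 for EB KO. The 28 single-cell libraries with counts held 35 to 2177 barcodes and 73979 to 15746383 counts each. The series design speaks of technical duplicates, and no label says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical.

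Esrrb (ENSMUSG00000021255) was low in each of the 6 bulk libraries labelled KO. It was not read in the ZHBTC4 single-cell libraries, whose transcript IDs could not be named here. In XEN differentiation it stood at 30.5, 31.3 and 35.1 CPM (counts scaled to a common library total) in the 3 WT libraries and at 2.73, 3.79 and 3.22 in the 3 KO libraries, a log2 fold change of −3.33 ± 0.19 (SE, edgeR adjusted p = 1.94e-05). In EBs it stood at 67.99, 64.9 and 110 CPM in WT and at 1.54, 1.11 and 0.919 in KO, a log2 fold change of −5.72 ± 0.29 (edgeR adjusted p = 3.95e-06). The libraries were primed with oligo dT, so counts from the 3′ end of the transcript need not report on the deleted part of the gene. The sample labels say KO without naming the gene; Esrrb comes from the series' design text.

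**Figure D1:**
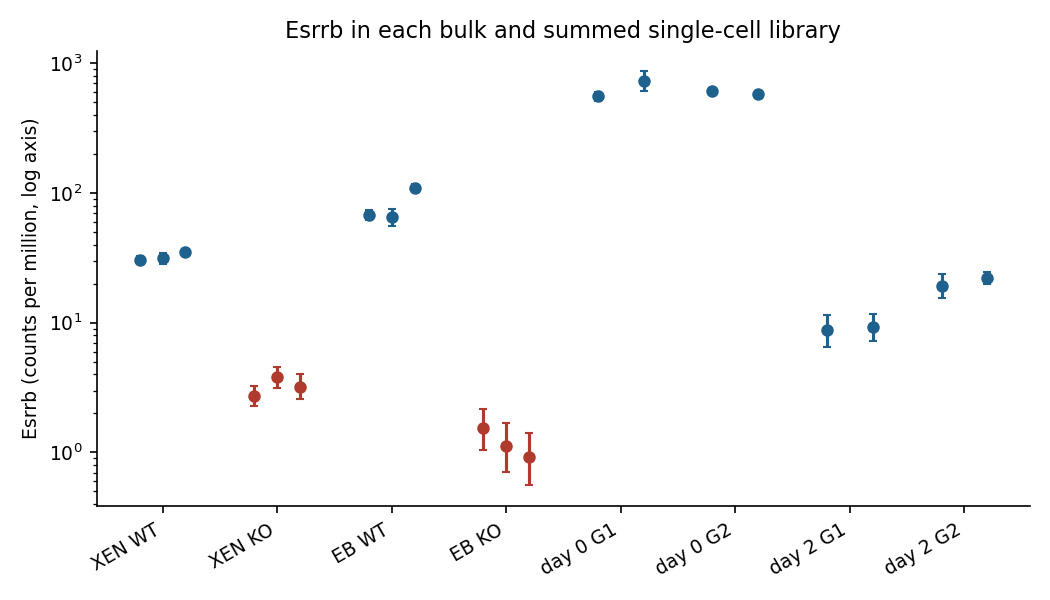
Esrrb in CPM (log axis) in each ZHBTC4 bulk library and each summed single-cell library of the R1 time series, with exact 95% Poisson intervals for counting error. The 6 KO libraries (red) sit between 0.919 and 3.79, the 6 WT libraries between 30.5 and 110, and the day 0 R1 libraries between 558 and 729.

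Under XEN differentiation much of the endoderm program was lower in the knockout, while the GATA factors Gata6 and Gata4 were higher. Of 23 measured genes of the XEN list, 14 fell, 5 rose and 4 did not pass the test (14 and 5 adjusted over the list alone), with a median log2 fold change of −1.23 and adjusted p = 0.0012 by camera. This became adjusted p = 0.158 with an estimated correlation. Lama1, a basement membrane laminin chain, fell by 4.00 ± 0.20 on the log2 scale (2.95 CPM in KO against 47.5 in WT). Gata6, the GATA factor that specifies primitive endoderm, rose by 1.90 ± 0.17 (243 against 65.2 CPM, edgeR, n = 3 and 3). Gata4 rose by 1.035 ± 0.162 (33.1 against 16.1 CPM), while Sox17 fell by 1.23 ± 0.37 and Foxa2 by 2.32 ± 0.19. Between the protocols, WT levels of endoderm genes ran both ways in a joint fit. Gata6 stood at 68.4 CPM in XEN WT and 32.3 in EB WT, and Col4a1 at 93.7 and 253. The visceral endoderm list also fell (6 of 11 members lower and none higher, also over the list alone, median −1.43, adjusted p = 0.0012, adjusted p = 0.0996 with an estimated correlation). Its largest changes were in Ttr and Fgb. Ttr, a carrier of thyroxine and retinol, stood at −5.08 ± 0.32 from a level of 8.09 CPM in WT. Fgb, a fibrinogen chain, stood at −5.02 ± 0.82 from a level of 0.757 CPM in WT. The parietal endoderm list was not called as a set (median 0.33, adjusted p = 0.695), with Krt19, a keratin, higher at 3.40 ± 0.23 and Stra6, the retinol transporter, lower at −4.16 ± 0.21.

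Neural genes were lower in the XEN-differentiated knockout. Of 19 neuroectoderm genes 13 fell, 3 rose and 3 did not pass (14 and 3 adjusted over the list alone), with a median of −1.75 and adjusted p = 6.88e-09. The call held at adjusted p = 0.0269 with an estimated correlation. Neurog1, a proneural bHLH factor, fell by 6.20 ± 0.36 on the log2 scale, and Map2, a microtubule-associated protein of neurons, rose by 1.89 ± 0.15. Sox2, shared by ES and neural progenitor cells, fell by 3.80 ± 0.17 (4.14 against 57.5 CPM), and Crabp1, a cytoplasmic retinoic acid binding protein, by 5.34 ± 0.24 (5.23 against 212 CPM). The primed epiblast list, which holds Crabp1, had a median of −0.47 (8 lower, 4 higher, 5 not passing of 17, 9 and 4 adjusted over the list alone, adjusted p = 0.00529, adjusted p = 0.0996 with an estimated correlation). The core pluripotency list had a median of −0.30 (4 lower, 2 higher of 9, also over the list alone, adjusted p = 0.0412, adjusted p = 0.158 with an estimated correlation). This core list call was lost without KO replicate 1 (0.0540), KO replicate 2 (0.0764) or KO replicate 3 (0.0653), and its median was −0.045 without WT replicate 2. Dppa2, a germ cell and ES cell factor of that list, rose by 1.14 ± 0.19. The naive list was not called (median −0.45, adjusted p = 0.0664). Tbx3, a T-box factor, rose by 1.71 ± 0.16 and Tdh, the mitochondrial threonine dehydrogenase, fell by 4.83 ± 0.27. Without WT replicate 3 the naive list passed (adjusted p = 0.0461), and leaving out 1 library moved its median to between −0.61 and −0.23. The 2-cell-like list was lower (4 of 6 members, also over the list alone, median −1.94, adjusted p = 0.0412, adjusted p = 0.158 with an estimated correlation), with a median of −3.02 without KO replicate 1. Zscan4f of that list stood at only 3.58 CPM in WT and 0.341 in KO. Zscan4c (0.567 in WT and 0.544 in KO) and Zscan4d (0.548 and 0.349) did not pass. Near-identical Zscan4 copies may share reads.

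The mitotic program was lower and stress-response genes were higher in the same knockout libraries. Of 24 G2/M genes 23 fell and 1 did not pass (23 adjusted over the list alone), with a median of −1.46, adjusted p = 2.79e-10 and adjusted p = 0.0269 with an estimated correlation. Cdc20, the activator of the anaphase-promoting complex, fell by 2.25 ± 0.18 and Bub1b, a spindle checkpoint kinase, by 2.36 ± 0.33. The G1/S list was lower too (16 lower, 3 higher of 22, also over the list alone, median −0.98, adjusted p = 0.00144, adjusted p = 0.0775 with an estimated correlation), with Cdca7 at −2.35 ± 0.22. Of 12 p53 target genes 9 rose and none fell (9 over the list alone, median 1.63, adjusted p = 1.92e-08, adjusted p = 0.0275 with an estimated correlation), led by Perp, a desmosomal protein and p53 target, at 4.53 ± 0.27, and Phlda3, a repressor of Akt, at 3.58 ± 0.21. Of 12 immediate early genes 11 rose (12 adjusted over the list alone, median 1.93, adjusted p = 1.36e-06, adjusted p = 0.0393 with an estimated correlation), among them the AP-1 subunit Fosb at 3.79 ± 0.33 and the MAP kinase phosphatase Dusp1 at 3.04 ± 0.21. Cyp26b1, which degrades retinoic acid, rose by 5.03 ± 0.26 (1660 against 50.8 CPM), while the retinoic acid response list as a set was not called (median 0.40, adjusted p = 0.806).

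The other lists were not called in XEN differentiation: mesoderm (median 0.51, adjusted p = 0.15), definitive endoderm (0.69, 0.207), trophoblast (0.74, 0.322), cardiac (−0.75, 0.646), blood (−0.70, 0.846), endothelium (0.40, 0.915), mesenchyme (1.02, 0.0857) and ribosomal proteins (−0.17, 0.695). Several of these medians moved with single libraries: leaving out 1 gave 0.65 to 1.13 for definitive endoderm, 0.33 to 0.93 for trophoblast, −0.78 to −0.16 for cardiac, −1.17 to −0.72 for blood, 0.14 to 0.48 for endothelium and −0.29 to −0.12 for ribosomal proteins. The parietal endoderm median then ran from 0.24 to 0.50 and that of retinoic acid response from 0.25 to 0.49, and none of these lists passed. Single members still moved in both directions, such as Peg10, a placental retrotransposon-derived gene, at 3.13 ± 0.25, and Tfap2c, a trophoblast and germline factor, at −2.11 ± 0.21. Cxcr4, a chemokine receptor, was higher at 2.41 ± 0.48 and Lhx1, a LIM homeobox factor, lower at −2.29 ± 0.30. Among genes whose libraries did not overlap and whose mean was at least 10 CPM in the higher group, the chemokine Ppbp (8.66 ± 0.50) and Spata5l1 (7.58 ± 0.70) had the largest rises that do not rest on a group at 0. Spink1, a secreted protease inhibitor (−6.35 ± 0.31), and the neural zinc finger factor Myt1 (−6.00 ± 0.30) had the largest falls of that kind. By edgeR 10236 of 19870 tested IDs were called, 5010 higher and 5226 lower (n = 3 and 3).

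In embryoid bodies pluripotency genes were lower and neural genes higher in the knockout. Of 19 naive pluripotency genes, a list that holds Esrrb itself, 17 fell and 2 did not pass (17 adjusted over the list alone), with a median of −2.37 and adjusted p = 2.81e-10. This became adjusted p = 0.443 with an estimated correlation. Fgf4, a growth factor made by naive cells, fell by 5.30 ± 0.42 on the log2 scale. Dppa4, an ES cell chromatin protein, fell by 3.35 ± 0.23 (edgeR, n = 3 and 3). Pou5f1, the core pluripotency factor, fell by 2.55 ± 0.23 (7.88 against 45.2 CPM). In XEN differentiation Pou5f1 rose instead, by 1.00 ± 0.21 (44.6 against 22.2 CPM). Counts of Pou5f1 may come from the transgene of this line. The core list fell with a median of −1.52 (7 lower, 1 higher of 9, also over the list alone, adjusted p = 0.000646, adjusted p = 0.53 with an estimated correlation). The 2-cell-like list, genes of the early embryo and of rare ES cells, fell in 10 of 11 members (10 over the list alone, median −3.63, adjusted p = 2.81e-10, adjusted p = 0.0756 with an estimated correlation). Zscan4f of that list stood at 1.85 CPM in KO against 49.8 in WT (−4.74 ± 0.17), with reads that the near-identical Zscan4 copies may share.

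Neuroectoderm genes rose in EBs: 19 of 20 were higher, also over the list alone, with a median of 2.55 and adjusted p = 5.67e-05. The set had adjusted p = 0.585 with an estimated correlation. Dcx, a microtubule protein of migrating neurons, rose by 4.70 ± 0.54 and Fabp7, a brain fatty acid binding protein, by 4.14 ± 0.52 on the log2 scale. Crabp1 rose by 3.56 ± 0.38 (1588 against 134 CPM), while Nodal, the TGF-beta ligand of the primed list, fell by 3.65 ± 0.43. Endothelial genes fell (8 of 10 lower, 1 higher, also over the list alone, median −2.05, adjusted p = 0.000215, adjusted p = 0.135 with an estimated correlation), with Cldn5, a tight junction protein of vessels, at −3.60 ± 0.39. Kdr, the VEGF receptor of early mesoderm, fell by 3.09 ± 0.15, and the alpha globins Hba-a1 and Hba-a2, near-identical copies, stood at −4.08 ± 0.48 and −3.84 ± 0.66. Alb, the serum albumin gene, rose by 6.74 ± 0.51 (437 against 5.07 CPM) in a visceral endoderm list that was not called (median 1.54, 7 higher and 2 lower of 15, also over the list alone, adjusted p = 0.307). That list passed without WT replicate 2 (median 2.73, adjusted p = 0.0366), and leaving out other libraries took its median down to 0.75 and its adjusted p up to 0.715.

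The p53 list was higher in EBs (9 of 12, or 10 adjusted over the list alone, median 0.56, adjusted p = 0.0443, adjusted p = 0.435 with an estimated correlation), with Cdkn1a, the p21 cell cycle inhibitor, at 1.24 ± 0.095. This call was lost without WT replicate 1 (0.0540), KO replicate 1 (0.0636), KO replicate 2 (0.0609) or KO replicate 3 (0.0544). The immediate early list was higher (8 higher, 1 lower of 12, also over the list alone, median 0.67, adjusted p = 0.0344, adjusted p = 0.532 with an estimated correlation), with the heat shock gene Hspa1b at 1.77 ± 0.099, and this call was lost without KO replicate 1 (0.0544). The G2/M list had a median of 0.04 (11 higher, 5 lower of 24, adjusted p = 0.718) and the G1/S list of 0.09 (10 higher, 6 lower of 22, adjusted p = 0.332). Not called either were XEN genes (median −0.54, adjusted p = 0.121), parietal endoderm (0.07, 0.735, the test points down), primed epiblast (median 0.47, mean −0.12, adjusted p = 0.459, the test points up), mesoderm (−0.77, 0.174) and definitive endoderm (0.26, 0.311). The same held for trophoblast (0.07, 0.772), cardiac (−1.02, 0.16), blood (−2.42, 0.0999), mesenchyme (−0.59, 0.658), retinoic acid response (median −0.03, mean 0.46, adjusted p = 0.332, the test points up) and ribosomal proteins (0.42, 0.0984). The XEN list passed without WT replicate 1 (0.00179), as did the retinoic acid list (0.0108). The blood list passed without WT replicate 3 (0.0338), and the ribosomal list without WT replicate 2 (0.0329) or WT replicate 3 (0.0251). Leaving out 1 library turned the small medians of parietal endoderm (−0.17 to 0.18), definitive endoderm (−0.00 to 0.62), trophoblast (−0.04 to 0.30) and retinoic acid response (−0.16 to 0.24), and moved those of G2/M (0.01 to 0.15) and G1/S (0.07 to 0.29). By edgeR 12861 of 19090 tested IDs were called, 6391 higher and 6470 lower. EB WT libraries were shallower than EB KO libraries, and thinning each library to the smallest total, chosen after seeing the data, left 4832 calls.

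**Figure D2:**
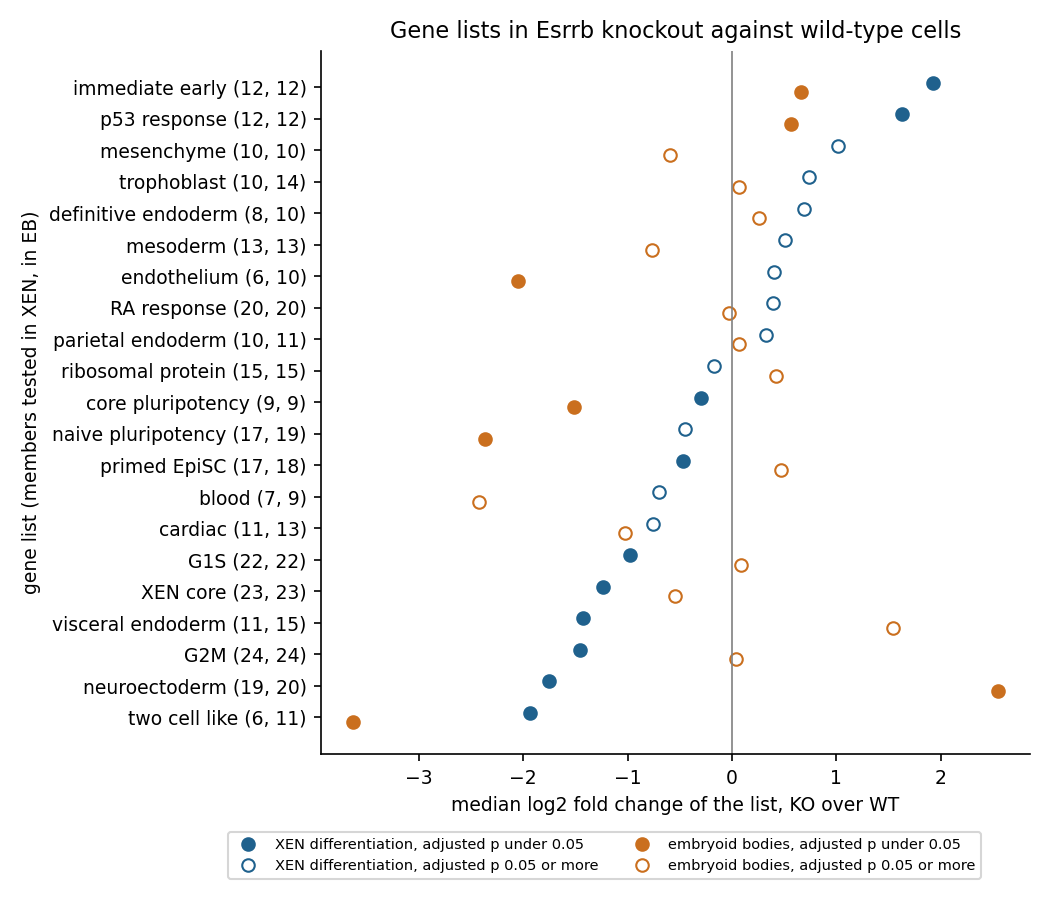
Median log2 fold change (KO over WT) of each fixed gene list in XEN differentiation (blue) and embryoid bodies (orange), 3 KO against 3 WT libraries each; filled points passed camera at an adjusted p under 0.05. Neuroectoderm sits at −1.75 in XEN and 2.55 in EB, G2M at −1.46 and 0.04, and naive pluripotency at −0.45 and −2.37.

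The knockout effect differed between the differentiation protocols for 12291 of 21394 tested IDs (edgeR interaction, 6167 with a higher and 6124 with a lower effect in XEN). With libraries thinned to the smallest total the count was 3063. Neuroectoderm genes had the largest median difference among the fixed lists: 18 of 20 had a lower effect in XEN than in EB and none a higher one, also over the list alone (median difference −3.95, adjusted p = 5.53e-11, adjusted p = 0.177 with an estimated correlation). Visceral endoderm genes had a lower effect in XEN (11 lower, 1 higher of 15, also over the list alone, median −3.37, adjusted p = 0.00613, adjusted p = 0.405 with an estimated correlation), a call that thinning ended (adjusted p = 0.0748). Naive pluripotency genes had a higher effect in XEN (13 higher, 3 lower of 19, also over the list alone, median 1.98, adjusted p = 0.000605, adjusted p = 0.289 with an estimated correlation), and that of Esrrb itself was 2.34 ± 0.34, a call that ended after thinning (edgeR adjusted p = 0.36). G2/M genes had a lower effect in XEN in 21 of 24 members (21 over the list alone, median −1.75, adjusted p = 3.5e-08, adjusted p = 0.00972 with an estimated correlation), and G1/S genes in 16 of 22 with 2 higher (17 and 3 over the list alone, median −1.11, adjusted p = 0.00105, adjusted p = 0.0644 with an estimated correlation). The p53 list (6 of 12 higher, also over the list alone, median 0.91, adjusted p = 0.00345) and the immediate early list (8 of 12 higher, also over the list alone, median 1.23, adjusted p = 0.0285) had a higher effect in XEN; adjusted p = 0.177 with an estimated correlation for both. The primed list differed with a median of −0.35 (8 lower, 5 higher of 18, also over the list alone, adjusted p = 0.0285, adjusted p = 0.177 with an estimated correlation), a call lost without XEN KO replicate 1 (0.0513). The endothelium list passed without XEN KO replicate 2 (0.0341) or EB WT replicate 3 (0.0447), and the mesoderm list without EB WT replicate 3 (0.0447). Among 17858 IDs tested in both, 1454 were higher in both protocols and 1336 lower in both, against 1526 and 1575 for independent calls. A further 1934 were lower in XEN and higher in EB, against 1666, and 1652 were higher in XEN and lower in EB, against 1443.

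The bulk R1 libraries carry transcript IDs that could not be paired with gene names here, so their comparisons give counts of IDs. At day 0, G2M cells were compared with late G1 cells (3 and 3 libraries). By edgeR 5142 of 16942 IDs were called, 2730 higher and 2412 lower in G2M. The transcript uc007jst.2 had no count in late G1 and a mean of 1201 CPM in G2M, and uc008ois.1 had none in G2M and 3744 CPM in late G1. Whether counts moved between transcripts of one gene could not be checked without gene names. The number of calls was 1211 without G2M replicate 3, 1268 without G2M replicate 2, 2708 without G2M replicate 1 and 3263 without late G1 replicate 3. The common biological coefficient of variation was 0.671, against 0.249 in the XEN and 0.148 in the EB libraries. Simulated counts for the day 0 comparison gave back 1 of 50 genes changed 4-fold and 11 of 50 changed 16-fold.

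At day 2 no ID was called between G2 and G1 by edgeR (2 and 2 libraries, 20705 IDs), with 689 at an unadjusted p under 0.05, while DESeq2 called 136. On simulated counts for this comparison none of the 50 genes changed at each of 2-, 4-, 16- and 64-fold was recovered. The same simulation recovered none at any of these folds for day 4 and for the difference between the days, where the real counts gave calls. At day 4 edgeR called 2223 IDs, 1618 higher and 605 lower in G2, among them uc008ztk.1 (3502 CPM in G2, no count in G1) and uc009mhh.1 (1834 CPM in G1, no count in G2). The transcript uc012acf.1 took 58.5% and 55.9% of all counts in the 2 day 4 G2 libraries, and G1 replicate 1 held 58302 counts. Without day 4 G1 replicate 1 the count was 6200 (2130 higher, 4070 lower), and without replicate 2 it was 1391. Leaving out a day 2 library gave 937 or 968 for G1 and 894 or 891 for G2. With RLE size factors the calls were 3110, 2625 higher and 485 lower, and the median log2 fold change of all IDs moved from −0.96 to 0.00, so directions at day 4 are relative to the scaling.

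Day 4 against day 2 gave 2859 calls by edgeR, 1039 higher and 1820 lower at day 4 (1594 and 1774 with RLE factors, where the median of all IDs moved from −1.15 to −0.65). Leaving out any of the day 2 libraries ended all calls, and leaving out day 4 G1 replicate 1 gave 5712. The G2 to G1 effect differed between the days for 764 IDs, 660 with a higher effect at day 4 (edgeR interaction, the median of all IDs moved from −1.10 to −0.13 with RLE factors). This count fell to 1 without either day 2 G1 library and to 0 without either day 2 G2 library, and stood at 4525 without day 4 G1 replicate 1 and at 1334 and 1160 without a day 4 G2 library. Sequencing batch may follow the day, since the days share no library.

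In the single-cell time series the sort at day 0 showed in the mitotic genes. Of 24 G2/M genes 23 were higher in G2 than in G1 cells (24 adjusted over the list alone), with a median log2 fold change of 3.26 and adjusted p = 5.65e-25 by camera on counts summed per library. The set had adjusted p = 0.575 with an estimated correlation. Mki67, the proliferation antigen, stood at 240 CPM in G2 and 7.10 in G1 (5.40 ± 0.57, edgeR adjusted p = 2.77e-10, n = 2 and 2), and Birc5, survivin, at 1102 and 36.7 (5.34 ± 0.53). Esrrb did not pass (558 and 729 CPM in G1, 617 and 576 in G2, 0.30 ± 0.38, edgeR adjusted p = 0.817), and neither did the naive list (median −0.00, 20 of 20 members not passing, adjusted p = 0.694, the mean of 0.17 and the test point up; median −0.14 to 0.15 with 1 library left out). Ribosomal protein genes were higher in G2 (median 0.87, 1 of 15 passing, or 9 adjusted over the list alone, adjusted p = 2.11e-05), as were G1/S genes (median 0.52, 1 of 22, or 3 over the list alone, adjusted p = 0.00686); adjusted p = 0.575 with an estimated correlation for both. The G1/S call was lost without G2 replicate 2 (0.066). Of 18793 IDs 326 were called by edgeR, 259 higher and 67 lower in G2. Without day 0 G1 replicate 1 the count was 79, without G1 replicate 2, a library of 35 cells, 47, without G2 replicate 1 116 and without G2 replicate 2 95. Mki67 and Birc5 passed in each.

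After 2 days of retinoic acid naive genes were lower and retinoid-response and endoderm genes higher than at day 0. Esrrb fell from a mean of 596 CPM at day 0 to 17.1 at day 2 (−5.26 ± 0.43, edgeR adjusted p = 5.04e-16). Of 20 naive genes 19 fell (20 adjusted over the list alone, median −4.32, adjusted p = 1.45e-29, adjusted p = 0.258 with an estimated correlation). Of 20 retinoic acid response genes 18 rose (19 over the list alone, median 4.71, or 4.19 with genes at 0 counts held at their bound, adjusted p = 5.68e-23, adjusted p = 0.356 with an estimated correlation). Cyp26a1, which degrades retinoic acid, was at least 4120-fold higher at day 2, and H19, an imprinted noncoding RNA, at least 23019-fold higher, each against 0 counts at day 0 and a floor of 3 counts over the group. Of 23 XEN genes 19 rose and 1 fell (20 and 1 over the list alone, median 2.94, adjusted p = 5.66e-17, adjusted p = 0.258 with an estimated correlation). Visceral endoderm (4 of 9 higher, also over the list alone, median 1.50, adjusted p = 0.00169, 0.408 as adjusted p with an estimated correlation) and parietal endoderm genes (5 of 10 higher, 2 lower, or 6 and 2 over the list alone, median 2.38, adjusted p = 0.00815, 0.39 as adjusted p with an estimated correlation) were higher as well. Without day 0 G1 replicate 1 the medians were 4.84 for XEN genes, 4.36 for parietal endoderm and 7.13 for retinoic acid response, and without day 0 G2 replicate 1 that of visceral endoderm was 2.76.

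Other lists moved with the day as well. The 2-cell-like list rose (10 of 13, or 11 adjusted over the list alone, median 7.51, or 4.74 with genes at 0 held at their bound, adjusted p = 4.99e-11, adjusted p = 0.428 with an estimated correlation), with Zscan4f at least 569-fold higher, among copies that may share reads. Averaged over G1 and G2, G2/M genes rose (18 of 24, or 20 over the list alone, median 1.33, adjusted p = 1.46e-07, adjusted p = 0.444 with an estimated correlation), as did mesenchyme (4 of 7, also over the list alone, median 2.54, adjusted p = 0.000876, adjusted p = 0.394 with an estimated correlation) and trophoblast genes (5 of 10 higher, 1 lower, or 6 and 1 over the list alone, median 1.90, adjusted p = 0.00823, adjusted p = 0.514 with an estimated correlation). The rise in G2/M genes did not run alike in the sorted stages: Mki67 went from 7.10 to 109 CPM in G1 and from 240 to 113 in G2. Of 2 more genes, chosen after their values were seen, the mitotic cyclin Ccnb1 went from 27.2 to 221 in G1 and from 226 to 128 in G2, and its kinase Cdk1 from 19.7 to 140.5 in G1 and from 292 to 320.5 in G2. Immediate early genes fell (7 of 12 lower, 1 higher, or 8 and 1 over the list alone, median −1.53, adjusted p = 6.86e-06, adjusted p = 0.39 with an estimated correlation). Foxd3, a forkhead factor of the epiblast, was at least 60.0-fold lower. By edgeR 4140 IDs were called, 2385 higher and 1755 lower at day 2, with 2 day 2 samples, 1 per stage, since libraries of one group that share cells were merged; the spread therefore comes from the day 0 libraries alone. Without day 0 G2 replicate 1 the count was 2712 and without replicate 2 it was 2372. The core list passed without day 0 G1 replicate 1 (0.0401), and the trophoblast median was then 3.62.

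After 2 days, G1 and G2 cells held 1 merged sample each, so the values describe those libraries and no test was made. The XEN list had a median log2 ratio of 0.34 (18 of 23 genes higher in G2, percentile 96.7 of 10000 random lists matched on expression). Gata6 stood at 203 CPM in G2 against 98.8 in G1, Lama1 at 158 against 49.2, and Esrrb at 21.5 against 9.03. The 2-cell-like list was lower in G2 in 13 of 13 genes (median −1.47, percentile 0), and the p53 list lower in 8 of 12 (median −0.83, percentile 0.07), including Mdm2, the p53 ubiquitin ligase, at 114 against 639 CPM. G2/M genes were lower in the G2 sample (15 of 24, median −0.34, percentile 1.3), the reverse of day 0, though Cdk1 stood at 320.5 CPM in G2 against 140.5 in G1 and Mki67 at 113 against 109. The mitotic genes thus ran both ways. An exchange of the G1 and G2 labels was not excluded, and it would turn each direction given for day 2, the shares of XEN-marker cells included.

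The share of cells with at least 3 different XEN genes, at 1000 counts per cell, followed the days of retinoic acid. At day 0 it was 2.15% in a G1 library (4 of 186 cells, exact 95% interval 0.589 to 5.41) and 0.165% and 0.234% in the G2 libraries. At day 2 it was 12.6% and 12.7% in the G1 libraries and 26.4% and 21.8% in the G2 libraries, which count as 1 sample per stage. Day 2 had a mean of 18.4% over 2 samples and day 0 of 0.85% over 3, a difference of 17.5 percentage points (exact permutation p = 0.1, two-sided, the smallest this design allows). Without thinning, the day 0 libraries held 17.5% to 34.3%. The highest value came from G1 replicate 2, a library of 35 cells that was given no share after thinning. Intervals on shares and counts cover counting error only, and a share defined by a number of markers is a range and not a cell type.

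At day 4 of retinoic acid in serum, the G2-sorted library held more XEN-marker cells than the G1-sorted ones. The share was 80.3% in G2 (416 of 518 cells, 76.6 to 83.6), 58.6% in late G1 (285 of 486, 54.1 to 63.1) and 53.5% in early G1 (214 of 400, 48.5 to 58.5), from 1 library per stage and without a replicate check. Without thinning the shares were 98.3%, 94.2% and 94.25%, so the size of the gap rests on the depth per cell. The XEN list was higher in G2 than in late G1 in 23 of 24 genes (median log2 ratio 1.21, percentile 100) and than in early G1 in 22 of 24 (1.41, percentile 100), and between late and early G1 its median was 0.01 (percentile 48.9). Lama1 stood at 523 CPM in G2 (Poisson interval 505 to 542) and 40.2 in late G1 (36.2 to 44.5), Gata4 at 150 (141 to 160) and 33.7 (30.1 to 37.7), and Tdh at 54.3 and 0.864. The trophoblast list was lower in G2 (median −1.06 against late G1, percentile 0), with Peg10 at 229 against 1078 CPM. G2/M genes were higher in G2 by a median of 0.22 against late G1 (percentile 98.2) and 0.46 against early G1 (percentile 100). They were higher in late than in early G1 by a median of 0.28 (percentile 98.7). These genes thus set G2 apart from late G1 no more than late from early G1. The core pluripotency list was higher in G2 than in late G1 (median 0.69, percentile 99.9), and Esrrb had 1 count in G2, 3 in late G1 and 5 in early G1.

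**Figure D3:**
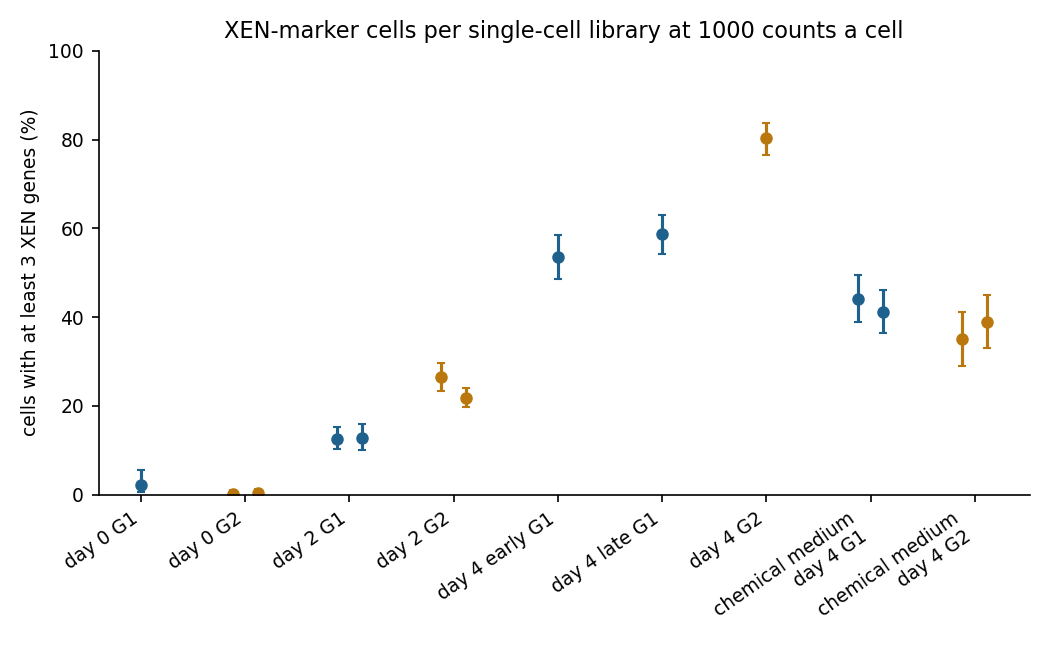
Percent of cells with at least 3 XEN genes after thinning each cell to 1000 counts, per single-cell library, G1 in blue and G2 in orange, with exact 95% intervals for counting error. The day 4 G2 library stands at 80.3%, the day 0 libraries at 0.165% to 2.15%, and the chemical medium libraries at 34.9% to 44.1%; the pairs of libraries at day 2 and of G1 in chemical medium share cells.

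In the chemically defined medium at day 4, the XEN, visceral endoderm and G2/M lists had lower medians in 2 G2 samples than in 1 merged G1 sample. For G2/M this is the reverse of the day 0 sort, though Mki67 stood at 267 CPM in G2 and 245 in G1. The 2 G1 libraries share 42.4% of barcodes, so G1 has no replicate: the spread comes from the G2 pair alone, and each test here assumes that G1 varies like it. An exchange of the G1 and G2 labels was not excluded, and it would turn each direction given for this medium. Col4a2, a basement membrane collagen, fell by 1.09 ± 0.26 on the log2 scale (552 CPM in G2, 1178 in G1, edgeR adjusted p = 0.00158, n = 2 and 1), Rbp4, the plasma retinol carrier, by 2.12 ± 0.44 and Cyp26a1 by 1.59 ± 0.27 (324 against 975 CPM). Sox4, an SRY-related factor, rose by 1.92 ± 0.30 (854 against 226 CPM) and Plagl1, an imprinted zinc finger gene, by 3.66 ± 0.54. Of 24 G2/M genes 3 fell and none rose (10 lower over the list alone, median −0.73, adjusted p = 6.16e-08, adjusted p = 0.876 with an estimated correlation), including the centromeric histone Cenpa at −1.41 ± 0.36. Of 24 XEN genes 2 fell (7 adjusted over the list alone, median −0.62, adjusted p = 0.00075, adjusted p = 0.876 with an estimated correlation), and of 10 visceral endoderm genes 2 fell (2 over the list alone, median −0.69, adjusted p = 0.0169, adjusted p = 0.876 with an estimated correlation). Of 15 ribosomal genes 5 fell (5 over the list alone, median −0.30, adjusted p = 0.000147, adjusted p = 0.876 with an estimated correlation). The visceral endoderm call was lost without G1 replicate 1 (median −0.35, adjusted p = 0.167). The ribosomal call was lost without G1 replicate 3 (median 0.03, adjusted p = 0.98), and its median was −0.62 without G1 replicate 1. The share of XEN-marker cells was 34.9% and 38.8% in G2 and 44.1% and 41.2% in the G1 libraries that share cells, a difference of −5.79 percentage points (exact permutation p = 0.667, the smallest p is 0.333). Esrrb did not pass (1.68 ± 1.6, edgeR adjusted p = 0.758), and 25 of its counts came from 1 cell. By edgeR 553 of 16149 IDs were called, 173 higher and 380 lower, with 1 residual degree of freedom from the G2 pair, against 196 by DESeq2.

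Late G1 cells at day 4 labelled Esrrb plus (2 libraries) and Esrrb minus (3 libraries), whose transcript IDs could not be named here, differed at no ID by edgeR (11936 tested, 1020 at an unadjusted p under 0.05), while DESeq2 called 263. Library plus 7 held 82 barcodes and 73979 counts and correlated with plus 5 at r = 0.48 across IDs. Without plus 5 the count was 4306 and without plus 7 it was 134. Leaving out minus 1, minus 2 and minus 3 gave 1, 9 and 45. On simulated counts for this comparison 13 of 50 genes changed 4-fold and 35 of 50 changed 16-fold were recovered.

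The ZHBTC4 single-cell KO and WT libraries after retinoic acid held 1 sample each, because the WT libraries shared all barcodes of the smaller one. Their log2 CPM values correlated at r = 0.793 across 3676 transcript IDs, which are not independent replicates. The largest ratios were uc007nsp.1 at 406 CPM in KO against 20.8 in WT and uc009kqq.1 at 66.5 against 3.07. Toward WT they were uc008vdl.2, with no count in KO and 54.8 CPM in WT, and uc008uuv.1 at 2.14 against 59.6. The separate day 4 G2 and G1 libraries of the R1 line correlated at r = 0.897 across 3866 IDs, and the day 2 ones, given as TPM, at r = 0.959 across 1927.

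At promoters, ChIP signal for H3K4me1 and H3K4me2, histone marks of enhancers and active promoters, was compared in KO and WT ES cells at day 0. Each region had 1 pooled value, scaled to the same total, and no test was made. The cells were not differentiated, so these values are of another stage than the XEN and EB RNA. The Gata6 promoter was higher in KO for both marks, with sums of 435 in KO and 182 in WT for H3K4me1 (scaled log2 ratio 0.79) and 1531 and 1087 for H3K4me2 (1.06). The Sox17 promoter stood at 0.34 and 0.40, Gata4 at −0.53 and −0.03, Esrrb at −0.39 and −0.10, Nanog at 0.10 and −0.18 and Pou5f1 at 0.06 and −0.21. Without scaling the Sox17 ratio for H3K4me2 was −0.17. Neuroectoderm promoters were lower in KO for H3K4me1 in 17 of 20 genes (median −0.47, percentile 0 of random lists matched on signal) and for H3K4me2 in 16 of 20 (median −0.27, percentile 0.05). Definitive endoderm promoters were lower for H3K4me2 (8 of 11, median −0.47, percentile 0.01) and trophoblast promoters higher (10 of 14, median 0.38, percentile 99.8). Naive (16 of 20 lower, median −0.27, percentile 0.48) and primed promoters (13 of 18 lower, median −0.27, percentile 0.08) were lower for H3K4me2. These list directions are relative to other promoters and to the scaling. Without scaling the median log2 ratio of all regions moved from 0.06 to 0.38 for H3K4me1 and from 0.07 to −0.44 for H3K4me2. The largest ratios were at Capn2, Zdhhc3 and Psd4 for H3K4me1 (2.21, 2.13 and 2.12) and at Gpr161, Pigz and Tagln2 for H3K4me2 (2.73, 1.96 and 1.95). The smallest were at 2210407C18Rik, Ccbe1 and Gm33934 (−2.99, −2.94 and −2.65) and at Gm33934, Nfix and Upp1 (−2.94, −2.67 and −2.65). Of 32771 regions 1564 differed by over 2-fold for H3K4me1 (843 higher, 721 lower) and 1569 for H3K4me2 (794 higher, 775 lower). This balance rests on the scaling: without it 2873 were higher and 260 lower for H3K4me1, and 164 higher and 3145 lower for H3K4me2. Among regions above the median signal, lower ones prevailed in both marks (343 higher and 453 lower, 116 and 270).

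The deposited H3K4me2 enhancer lists of these ES cells held 82373 regions in KO, covering 130.278 Mb, and 80599 in WT, covering 141.619 Mb. Mean values per region were 92.8 and 110. Of the KO regions 78.6% overlapped a WT region by at least 1 base, and 77.6% of the WT regions overlapped a KO region.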

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

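The tests of thinned libraries, of 2-cell genes, of ribosomal genes and of other splits were chosen after the results were seen; those of the implied ES cell share and of the most abundant IDs were written before.

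The effect of the knockout differed between XEN differentiation and embryoid bodies for 12291 IDs by an interaction test, which is what singled this comparison out. Of 100 splits of the 12 libraries, 1, the real one, gave as many calls (highest other 4725), the smallest share these splits allow. Every other split puts KO and WT libraries in one group, so the knockout effect itself widens the spread within groups and lowers the calls. The splits therefore cannot decide whether the difference between the protocols exceeds chance, and no conclusion is drawn from them. Thinned libraries, where fewer IDs were called, were not split. If replicates are technical, chance differences between cultures or clones are not covered by these splits. The gene lists that differed by camera on the same contrast had median differences (XEN effect minus EB effect) of −3.37 for visceral endoderm, 1.98 for naive pluripotency, −0.35 for primed epiblast, −3.95 for neuroectoderm, −1.75 for G2/M, −1.11 for G1/S, 0.91 for p53 targets and 1.23 for immediate early genes. Of these 8 lists 1, G2/M, also passed with an estimated correlation (adjusted p = 0.00972). In the R1 bulk libraries the G2 to G1 effect differed between day 4 and day 2 for 764 IDs, a count that leaving out 1 library moved to between 0 and 4525. For day 0 G2M against late G1 (5142 calls), XEN (10236) and EB (12861), 1 of 10 splits gave as many calls and the highest other gave 0, and 10 splits are too few for a share under 0.05.

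Pluripotency and 2-cell genes were higher in WT than in KO embryoid bodies. For the naive and core genes, 78.6% (22 of 28) had a WT minus KO difference within 4-fold of the median share, 15.0%, of their day 0 ES cell level. The shares ran from −93.4% to 89.9%. ES cells remaining in the WT bodies may account for these genes, but the window is wide and does not single out that source. The 28 genes include Esrrb, the knocked-out gene, and Pou5f1, a transgene in this line, whose differences need not report on remaining ES cells. Of the 2-cell genes 11 of 11 lay above the day 0 level in WT bodies. Zscan4a, Zscan4c, Zscan4d, Zscan4f, Tcstv1, Tcstv3 and Gm4340 stood at 0 CPM at day 0, so any count lay above it and they decide nothing. The members with counts at day 0 argue weakly against remaining ES cells as their source. These were Tmem92 (18.2 CPM in WT bodies, 0.046 at day 0), Usp17lc (16.6 and 4.31), Zfp352 (4.56 and 1.13) and Usp17ld (1.86 and 1.00). With libraries thinned to the smallest total the naive median was −2.68, so the fall in naive genes was there at equal depth too. The day 0 level comes from summed single cells of the R1 line, another line and assay, and an effect of Esrrb on exit from pluripotency or on the 2-cell-like state stays open and untested.

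Neuroectoderm genes were lower in XEN KO and higher in EB KO. Thinning left a median difference of −3.32, so the difference was there at equal depth too. The share taken by the 10 most abundant IDs can shift values by at most 0.028 log2, which argues against a few dominant genes as the cause. A different mix of cell types in the protocols, or an effect of the knockout on it, stays open, as bulk libraries do not separate cell types.

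In XEN KO, G2/M genes were lower and p53 and immediate early genes higher. A scaling error would move ribosomal protein genes alike, and their median was −0.17 against −1.46 for G2/M genes. Thinned libraries gave a G2/M median of −1.44, so the fall was there at equal depth too. Random thinning hardly moves the ratio of well-counted genes, so this value was likely in advance. Stress from handling or dissociation, and slower growth of the knockout line, may each give this pattern and were not tested; the lists do not separate them.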

How the results depend on the processing

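Thinning to the smallest total, summed symbols, libraries of the same cells kept apart, removal of a dominating ID and the 2 other overlap rules were chosen after seeing the data. In XEN differentiation each alternative run kept the count of calls within 1.5 times (7774 to 11608), and in EBs and for the difference of effects each did except thinning (4832 and 3063 calls). Of 1941 values for named genes under alternatives, 1849 kept direction and side of the threshold, 90 lost the call and 2 turned: in EBs Nnt was 0.78 with same-symbol IDs summed, since its second ID then enters, and Cdh5 was −0.0267 after thinning. Of 1873 values for lists 1750 kept their side of the threshold, 50 gained and 73 lost a call. Direction was compared for lists only where both runs made a call, and for named genes where either run did. The ChIP values were less stable: 56 of 125 list values and 20 of 48 promoter values moved. Where a cause is not given it was not tested. Depth limits the day 4 bulk groups (58302 counts in one library), Esrrb plus 7 (73979) and day 0 G1 replicate 2 (35 cells).

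With DESeq2 the calls were 136 for bulk day 2, 4440 for bulk day 4, 6577 for day 4 against day 2, 3220 for the difference between days, 263 for Esrrb plus against minus, 196 in chemical medium, 142 for single-cell day 0 and 2190 for day 2 against day 0. RLE factors gave 1884 for the difference between days. With no filter on low counts they were 2768 for bulk day 0, 900 for bulk day 4, 1080 for day 4 against day 2, 213 for the difference and 422 for Esrrb plus. One fit of all 14 R1 bulk libraries gave 1592 at day 0, 18 at day 2, 5364 at day 4, 6208 for day 4 against day 2 and 2783 for the difference. Fits of that day alone gave 1463 for bulk day 4 and 40 for single-cell day 0. Without the dominating ID the difference gave 1681. Barcodes with at least 2000 counts gave 136 for Esrrb plus. Summed symbols gave 272 in chemical medium. Keeping libraries of the same cells apart gave 493 for day 0 and 7364 for day 2 against day 0.

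Leaving out each library gave 1211 to 6090 calls for bulk day 0, 0 at bulk day 2 in each case (edgeR; 689 at an unadjusted p under 0.05 with all libraries), 891 to 6200 for bulk day 4, 0 to 5712 for day 4 against day 2, 0 to 4525 for the difference, 1 to 4306 for Esrrb plus, 47 to 361 for single-cell day 0 and 2372 to 4605 for day 2 against day 0. A lone sample left in a group is assumed to vary like the other groups.

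With the replicate number as a block the calls were 0 for bulk day 0 (edgeR, 5863 at an unadjusted p under 0.05; DESeq2 without the block called 7413) and 248 for bulk day 4. Same-numbered libraries did not deviate together in bulk day 0 (r = −0.05, −0.08 and 0.11) or XEN (−0.28, −0.23 and 0.12), and in EBs each correlated best with its own number at r of 0.05, 0.01 and 0.02. With 2 pairs r was 0.02 at bulk day 2, 0.07 at bulk day 4 and 0.18 at single-cell day 0, so the numbers were not taken as pairs. No paired analysis was possible for chemical medium and Esrrb plus because their groups share fewer than 2 numbers. A block was not run for day 4 against day 2, day 2 against day 0 or the differences of effects.

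The share of XEN-marker cells between G2 and G1 in chemical medium was −0.405 points with 2 markers, −10.7 with 4, 1.11 without thinning and −14.2 by clusters. For day 0 it was −1.95 points in the main setting, −11.1 with 2 markers, 0 with 4 markers, −5.97 thinned to 2000 counts, −3.48 without thinning and 0 by clusters. For day 2 it was 11.4 in the main setting, 15.5 with 2 markers, 9.45 with 4 markers, 17.2 thinned to 2000 counts, 14.0 without thinning and 13.5 by clusters. Day 2 minus day 0 was 37.4 without thinning. For RA day 4 the shares in G2, late G1 and early G1 were 91.1%, 78.8% and 78% with 2 markers, 63.7%, 35.8% and 30% with 4, and 90.9%, 77.4% and 71.75% thinned to 2000 counts. By clusters they were 68.9%, 23.7% and 20%, but 1 of the 3 clusters counted as XEN has no XEN gene among its top 10 genes and takes 62.9% of its cells from the G2 library.

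Promoter regions beyond 2-fold numbered 3761 (H3K4me1) and 3426 (H3K4me2) with a pseudocount of 1, 3133 and 3309 without scaling, which moves the median log2 ratio from 0.06 to 0.38 and from 0.07 to −0.44, and 796 and 386 among regions above the median signal. The overlap of enhancer lists was 80.5% above each list's own median and 61.4% where at least 50% of both regions overlap. Not run were the tests of ZHBTC4 single cells, day 2 G2 against G1 and its difference between days, since groups hold 1 sample, and of RA day 4, since the IDs of its libraries could not be joined, with their alternatives. As planned, with libraries of the same cells apart, the tests other than RA day 4 call 1556 IDs for ZHBTC4, 2208 for day 2 and 825 for the difference. Leaving out a chemical medium G2 library leaves no residual degrees of freedom.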

Other observations

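The gene families and their comparisons in this part were all chosen after the data were seen.

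Homeobox genes of the posterior Hox groups, which pattern the trunk and tail, moved in opposite directions in the knockout of the 2 protocols. In EBs 9 of 10 tested genes of Hox groups 10 to 13 were lower and none higher (median log2 fold change −5.11), led by Hoxd11 at −6.22, while in XEN differentiation 8 of 9 were higher and 1, Hoxb13, lower (median 2.67), with Hoxd11 at 3.55 and Hoxd13 at 3.99. The difference between the effects passed for 10 of 11 genes, 9 higher and 1 lower in XEN (median 4.71, edgeR interaction). Some levels in XEN were near the floor: Hoxd11 stood at 0.181 CPM in WT and 2.04 in KO, against 21.2 and 0.271 in EBs. Others were higher, with Hoxd13 at 1.43 and 23.7 CPM and Hoxc13 at 4.32 and 41.4 in XEN. Hoxa11 was not tested in XEN alone. Its difference of 9.54 rests on 0 CPM in XEN WT and 0.114 in XEN KO. Hox groups 1 to 9, which pattern the hindbrain and anterior trunk, were higher in EBs in 17 of 25 genes and lower in 3 (median 1.37), among them Hoxa2 at 3.13 and Hoxb3 at 2.97. In XEN 12 of 27 were higher and 4 lower (median 0.54). With RLE factors and with DESeq2 these directions were the same, except that the 1 lower call in the difference was not made by DESeq2.

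Genes of the prolactin family, hormones of placental giant cells, were higher in EB KO in 18 of 19 tested genes and lower in none (median 3.21), and in 3 of 3 in XEN (median 2.28), also with RLE factors and with DESeq2. Levels were far apart: Prl2c3 stood at 0.35 CPM in WT and 1.51 in KO under XEN differentiation, and at 52.5 and 1545 in EBs. Of 21 genes tested for the difference of effects 5 had a lower effect in XEN by edgeR and 9 by DESeq2, and none a higher one. Reads may be shared among these close copies, and with every library thinned to the smallest total the count of all calls in EBs was 4832.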
